A study of Homo sapiens with 6 samples.

How the data were processed

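RNA from HaCaT keratinocytes was measured on 6 Affymetrix Human 2.0 ST arrays, 3 of control and 3 of M1-treated samples, with groups and replicate numbers taken from the sample titles. The dose of M1 protein was 5 µg/ml and the exposure 6 h, per the labels. The deposited values are log2 RMA signals, 1 per probe set and array, made with Affymetrix Expression Console 1.1.2 and RMA, per the submitters' processing notes. RMA subtracts background, normalises between arrays and summarises the probes of a set, so values near the floor are compressed and fold changes of dim genes tend to be understated. How the 22119 probe sets of the value table were picked from the array is not given in the sources used here. The number of arrays limits the precision, and no column of another series was present.

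The authors' deposited table lists 497 probe sets with gene names, annotation and signals. Per the file headers, it gives a SAM score, the fold change as a ratio of the means of unlogged signals, a q-value (0 in every line) and a t-test p-value from the t-distribution with an alpha of 0.01. Its log2 signals were identical to the value table. Recomputing the table from the signals returned the same 497 of 497 probe sets with a SAM score of at least 1.03 or at most -1.00 and an unequal-variance t-test p under 0.001. The score limits were read from the listed probe sets, and the p limit lay just above their largest p, so all 497 had to pass. Only the absence of further probe sets within these limits is informative. The SAM constant recovered from the deposited scores was 0.667, larger than the standard error of 100% of the probe sets, so the score followed mostly the size of the log2 change. The limit in the table's name, 0.0001, differs from both the alpha in the header and the rebuilt limit, and which the authors meant is unresolved. The largest p-value in the authors' table was 0.000999 and the smallest fold change either way 1.63.

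Gene names came only from that table. They were updated through their accessions without version numbers against a RefSeq gene table of assembly GRCh38.p14: 476 of 497 matched, 46 of these had a newer symbol (IL8 is now CXCL8, CTGF is CCN2), and 21 kept the name in the file. The coordinates in the table name no build and were not converted. Of genes with 2 probe sets, AREG was represented by the brighter; those of F8A1 held identical values, so either gives the same result.

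Each probe set was fitted in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes), M1 against control, with no filter, and two-sided p-values were adjusted by Benjamini-Hochberg over all 22119 probe sets. Probe sets with an adjusted p under 0.05 were called. The prior had 3.11 degrees of freedom. The fit was tested on simulated data with the real means and spreads of the 22119 probe sets, 200 of them changed: it recovered 50 of 100 changes of 0.5 on the log2 scale and 93 of 100 changes of 1, with 8 false calls and 0 wrong signs. The simulated noise was independent between probe sets, and the real fit called far more probe sets, 7245. These figures therefore do not give the recovery or false calls in the real data.

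The test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, per direction, the 12 genes with the largest log2 change among called probe sets with 1 symbol and groups that do not overlap, and up to 4 called members of each list; a few results it gave are not reported here. Histone, small nucleolar RNA and ribosomal protein genes were given as counts. Of 30 lists, 27 had a fixed size. The planned set tests, camera and fry, need the names of probe sets that were not selected, and were not run. In their place, chosen after the data were seen, each list's number in the authors' table was tested with the hypergeometric test against all 22119 probe sets (Benjamini-Hochberg over 27 lists). The direction of lists with at least 3 members in the table was tested with Fisher's exact test against the other genes of the table (over 13 lists). A list member that the array does not carry counts as not in the table, which by itself makes the over-representation test conservative. Unnamed probe sets of the background that could never be list members, and list members that move together, would make its p-values too small. The net effect was not tested.

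The alternatives were the replicate number as a block, quantile normalization, median centring, removal of probe sets below the 25th percentile of mean signal, only named probe sets, an intensity trend or a robust variance prior, array weights, an equal-variance t-test, a SAM-type statistic over all 20 relabelings, a 1.5-fold limit, the mean of all probe sets of a gene, and each sample left out in turn. Added after the data were seen were the authors' selection as rebuilt, its score limits alone, an unequal-variance t-test with Benjamini-Hochberg, a background of brighter probe sets and a wider group of zinc finger genes. Permutation tests used 10000 or 100000 draws with fixed seeds. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.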

Results

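HaCaT cells, an immortalised line of human skin keratinocytes, were left untreated or kept for 6 h with 5 µg/ml of M1 protein, a surface virulence protein of the bacterium Streptococcus pyogenes. RNA of 3 control and 3 M1 samples, called biological replicates in the labels, was measured on Affymetrix Human 2.0 ST arrays, and these 6 had been picked from 12 after a check of RNA integrity. No source used here says whether the replicates were grown on separate days, so the p-values measure the spread between these samples. Each array gave a log2 RMA signal for 22119 probe sets, and the array medians were 6.99 to 7.01 in control and 6.93 to 6.96 with M1 protein. Across probe sets, Pearson's r was 0.996 to 0.997 between control arrays, 0.994 to 0.995 between M1 arrays and 0.977 to 0.981 between the groups. The first principal component held 74.5% of the variance and put the control arrays between -29.1 and -28.2 and the M1 arrays at 26.7, 32.8 and 26.5. Gene names came with 497 of the probe sets, all of them listed by the authors because they differed between the groups, so every statement on a named gene or gene list concerns that selection.

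The comparison asked which transcripts differ between keratinocytes with and without M1 protein. The largest rise was that of CXCL8, the neutrophil-attracting chemokine interleukin-8, from a log2 signal of 7.31 ± 0.25 (SD, n = 3) in control to 12.36 ± 0.19 (SD, n = 3) with M1 protein, a 33.1-fold difference. CCL20, a chemokine that attracts dendritic cells and lymphocytes, rose 20.1-fold, from 4.43 ± 0.18 to 8.76 ± 0.28 (SD, n = 3 each). HAS2, which makes hyaluronan, rose 17.8-fold, from 6.21 ± 0.22 to 10.36 ± 0.13 (SD, n = 3 each). Among the named genes the largest fall was that of ZNF681, a zinc finger gene, which was 5.37-fold lower, at 7.55 ± 0.19 in control and 5.13 ± 0.14 with M1 protein (SD, n = 3 each). The limma adjusted p-values (Benjamini-Hochberg over 22119 probe sets) of these 4 genes were 3.51e-06 for CXCL8, 9.28e-06 for CCL20, 4.04e-06 for HAS2 and 2.19e-05 for ZNF681. The control signal of CCL20 and the M1 signal of ZNF681 lay below the 25th percentile of every array (5.71 to 5.79). Of the genes given below, the mean control signals of LOC100131774, CXCL1, CXCL3, CSF2, IL20 and NR4A1 lay there too. So did the mean M1 signals of ZNF230, ZNF429 and FAM86JP, and the mean control signals of the unnamed probe sets 16743735 and 16788697. The sizes of all these folds are less certain.

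The other 9 of the 12 named genes with the largest rises lay between 3.10 and 3.46 on the log2 scale, each with a limma adjusted p of 5.23e-05 or less. They were the metalloprotease gene ADAMTS1 (3.46 ± 0.12 SE), the small GTPase gene GEM (3.41 ± 0.09 SE), TNFAIP3 (3.40 ± 0.07 SE), the chemokine CXCL1 (3.33 ± 0.20 SE) and the matricellular gene CCN2 (3.29 ± 0.12 SE). HBEGF (3.25 ± 0.07 SE), the secreted glycoprotein gene STC1 (3.17 ± 0.08 SE), ARL14 (3.16 ± 0.15 SE) and LOC100131774 (3.10 ± 0.16 SE) completed the set. LOC100131774, annotated on the plus strand of chromosome 6 from 132269313 to 132269801, overlaps CCN2, which lies on the minus strand from 132269316 to 132272518, so the rises of both cannot be taken as independent. The authors' table placed CXCL8 on chromosome 4 from 74606223 to 74609433 and ZNF681 on chromosome 19 from 23921997 to 23941693. The genome build of these coordinates is not given in the sources used here.

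**Figure D1:**
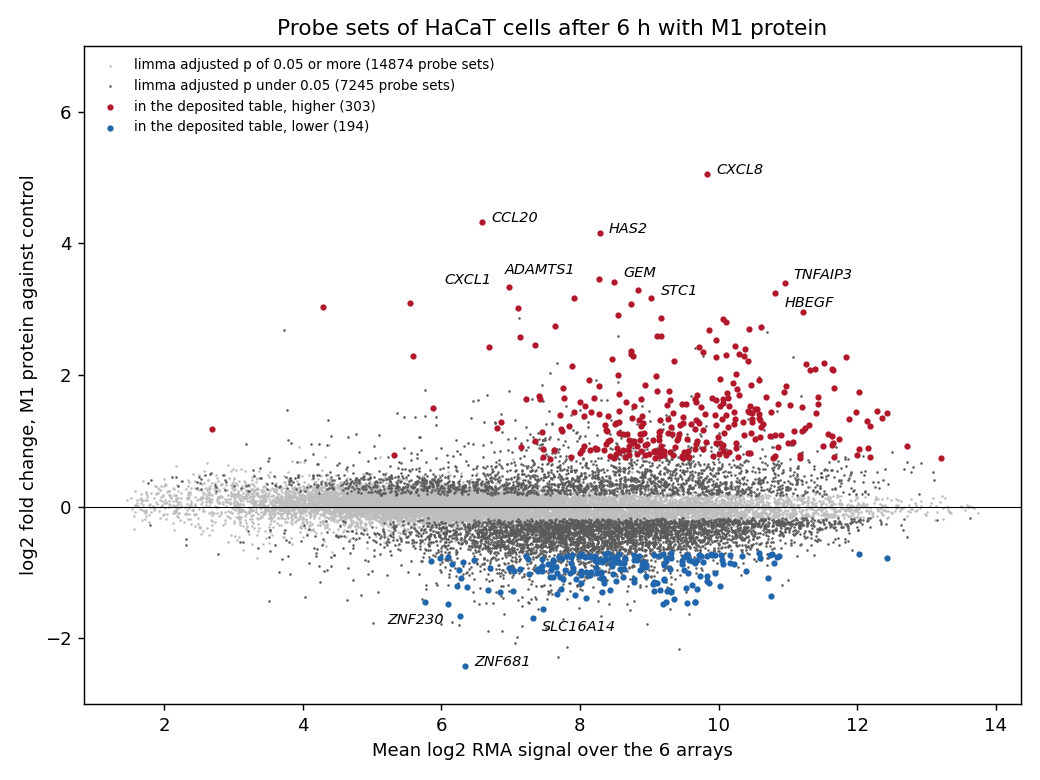
Each point is a probe set, with its mean log2 RMA signal over the 6 arrays on the x axis and its log2 fold change, M1 protein against control, on the y axis. Grey points stand for probe sets at or over a limma adjusted p of 0.05 (light) and under it (dark), and red and blue points for the 303 higher and 194 lower probe sets of the authors' table; CXCL8 stands highest at 5.05 and ZNF681 lowest of the named ones at -2.43.

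A further 10 of the largest falls among named genes were 2.61-fold to 3.24-fold, each with a limma adjusted p of 0.000318 or less. SLC16A14, of the monocarboxylate transporter family, fell by 1.69 ± 0.08 (SE) on the log2 scale. The zinc finger gene ZNF230 fell by 1.66 ± 0.07 (SE), ZNF429 fell by 1.48 ± 0.07 (SE) and ZFP3 fell by 1.38 ± 0.09 (SE). FANCF, a Fanconi anaemia DNA repair gene, fell by 1.56 ± 0.08 (SE), and the homeobox gene DLX3 fell by 1.46 ± 0.14 (SE). KIF20A, a mitotic kinesin, FAM86JP and F8A1 each fell by 1.45 ± 0.07 to 0.08 (SE), and HPS3, a gene of lysosome-related organelles, fell by 1.41 ± 0.07 (SE). F8A1 belongs to near-identical copies on chromosome X, and 2 probe sets of that name held the same values, so which copy was measured is open.

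**Figure D2:**
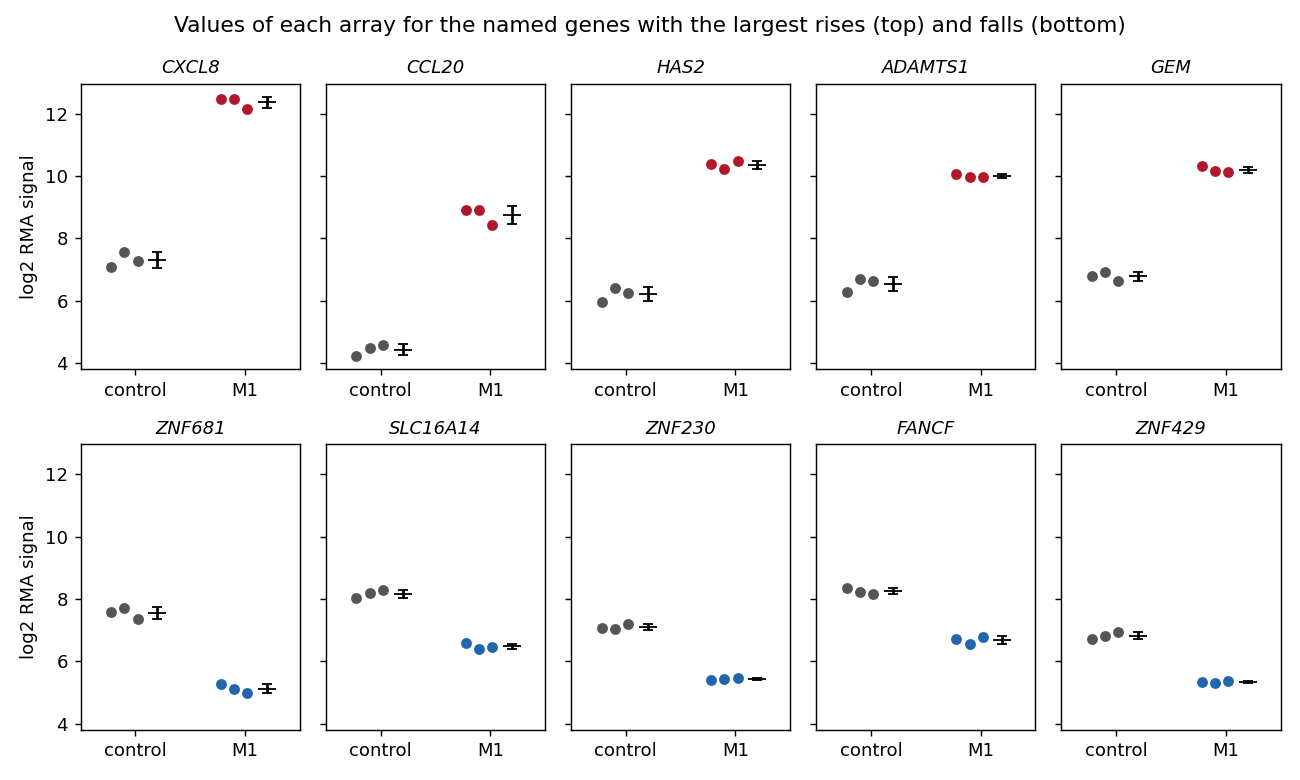
Log2 RMA signal (y axis) of each of the 3 control and 3 M1 arrays, with the mean and SD beside them as a bar, for 5 named genes with the largest rises and 5 with the largest falls. The rule that picked these genes required all M1 arrays to lie on the same side of all control arrays. CXCL8 lay at 7.31 ± 0.25 in control and 12.36 ± 0.19 with M1 protein (SD, n = 3 each).

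Chemokine and cytokine genes in the authors' table were higher, with no value here for the other members of their lists. Of 16 chemokine genes, 4 were in the authors' table and all 4 were higher: CXCL8, CCL20, CXCL1 and CXCL3, which rose 2.83-fold. Of 24 interleukins and other cytokines, 7 were in the table and all were higher, among them IL24 (log2 fold change 2.46 ± 0.16 SE), IL20 (2.43 ± 0.18 SE), CSF2, which encodes the growth factor GM-CSF (2.30 ± 0.15 SE), and IL1B (2.24 ± 0.10 SE). Of 24 genes of the NF-kappaB pathway and its targets, 6 were in the table and higher, led by TNFAIP3, an inhibitor of NF-kappaB signalling, and by BIRC3 (2.59 ± 0.12 SE), REL (1.29 ± 0.08 SE) and NFKB1 (0.94 ± 0.07 SE). Pattern recognition receptors and adaptors went both ways: of 24 genes, TLR4 (1.44 ± 0.13 SE), TICAM1 (1.01 ± 0.06 SE) and MYD88 (0.92 ± 0.07 SE) were higher, and TLR3 fell by 0.75 ± 0.07 (SE). Against all probe sets, these 4 lists were over-represented in the table (hypergeometric exact test, one-sided, Benjamini-Hochberg over 27 lists), with adjusted p = 0.00111 for chemokines, 6.2e-06 for cytokines, 5.36e-05 for NF-kappaB and 0.0046 for the receptors. Their direction did not pass Fisher's exact test against the rest of the table (two-sided, adjusted p = 0.21, 0.121, 0.16 and 1). Most other genes of the table were higher too (298 against 193 lower beside the chemokines). The unadjusted p of the same test was therefore 0.16 for chemokines and 0.0862 for NF-kappaB even with every member higher. For these 2 lists the test could not pass upward, so its failure says nothing against a common rise. CXCL1 and CXCL3 are close in sequence and may share signal.

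Immediate early genes, mostly of transcription factors, which cells switch on within minutes to hours of a stimulus, made up the fullest list. Of 22 such genes, 18 were in the table and all 18 were higher, from 0.75 for KLF4 to 3.08 ± 0.10 (SE) for NR4A2 on the log2 scale, with NR4A1 at 3.01 ± 0.09 (SE), FOSB at 2.87 ± 0.06 (SE) and ATF3 at 2.59 ± 0.07 (SE). The adjusted p was 2.86e-25 for over-representation and 0.00298 for the excess of higher over lower members against the rest of the table (Fisher's exact test, two-sided, over 13 lists). No other list passed that test of direction, where the adjusted p of the other lists was 0.0567 or more. MAP kinase feedback inhibitors, which switch the kinases off, followed with 8 of 15 genes, all higher (adjusted p = 4.65e-09 for over-representation): DUSP1 at 2.96 ± 0.06 (SE), DUSP5 at 2.80 ± 0.09 (SE), DUSP4 at 2.68 ± 0.07 (SE) and SPRY2 at 2.21 ± 0.08 (SE) led it.

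Of 11 genes of EGF receptor ligands and receptors, 5 were in the table and all were ligands and higher: HBEGF, EREG (2.16 ± 0.08 SE), TGFA (1.39 ± 0.07 SE), AREG (1.35 ± 0.08 SE) and NRG1, a ligand of related receptors (adjusted p = 1.57e-05 for over-representation). Of 21 genes of wound keratins and matrix remodelling, 6 were in the table and higher (adjusted p = 2.75e-05): HAS2, the urokinase receptor gene PLAUR (1.19 ± 0.06 SE), KRT17 (2.15-fold) and HAS3 (1.06 ± 0.06 SE) rose most. The list of hypoxia and glycolysis genes had 4 of 16 in the table, all higher (adjusted p = 0.00111): VEGFA (1.88 ± 0.06 SE), ADM (1.52 ± 0.07 SE), PFKFB3 (1.09 ± 0.06 SE) and HK2 (1.02 ± 0.05 SE). VEGFA and ADM encode secreted vascular factors and the other genes encode enzymes of glucose use. Of 16 genes of the unfolded protein and ATF4 response, PPP1R15A (2.70 ± 0.06 SE), DDIT3 (1.84 ± 0.10 SE) and DNAJB9 (0.86 ± 0.07 SE) were higher (adjusted p = 0.0105). Of 12 p53 target genes, BTG2 (1.55 ± 0.08 SE), the death receptor gene TNFRSF10B (1.03 ± 0.07 SE) and the cell cycle inhibitor CDKN1A (0.92 ± 0.07 SE) were higher (adjusted p = 0.0048).

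Of 20 mitosis genes, 5 were in the table and all were lower: KIF20A, the kinase gene PLK1, which fell by 1.35 ± 0.06 (SE), the cyclin gene CCNA2, which fell by 1.09 ± 0.08 (SE), CDCA8, which fell by 1.01 ± 0.08 (SE), and CCNB1. The adjusted p was 0.000254 for over-representation and 0.0567 for the direction by Fisher's exact test, so their common direction did not pass. Of 22 DNA replication genes, 4 were in the table and lower: of the replicative helicase genes, MCM6 fell by 1.23 ± 0.07 (SE), MCM3 fell by 1.13 ± 0.08 (SE) and MCM2 fell by 0.83 ± 0.07 (SE), and GINS1 fell by 1.01 ± 0.07 (SE). Their adjusted p was 0.00361 for over-representation and 0.0823 for the direction by Fisher's exact test.

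**Figure D3:**
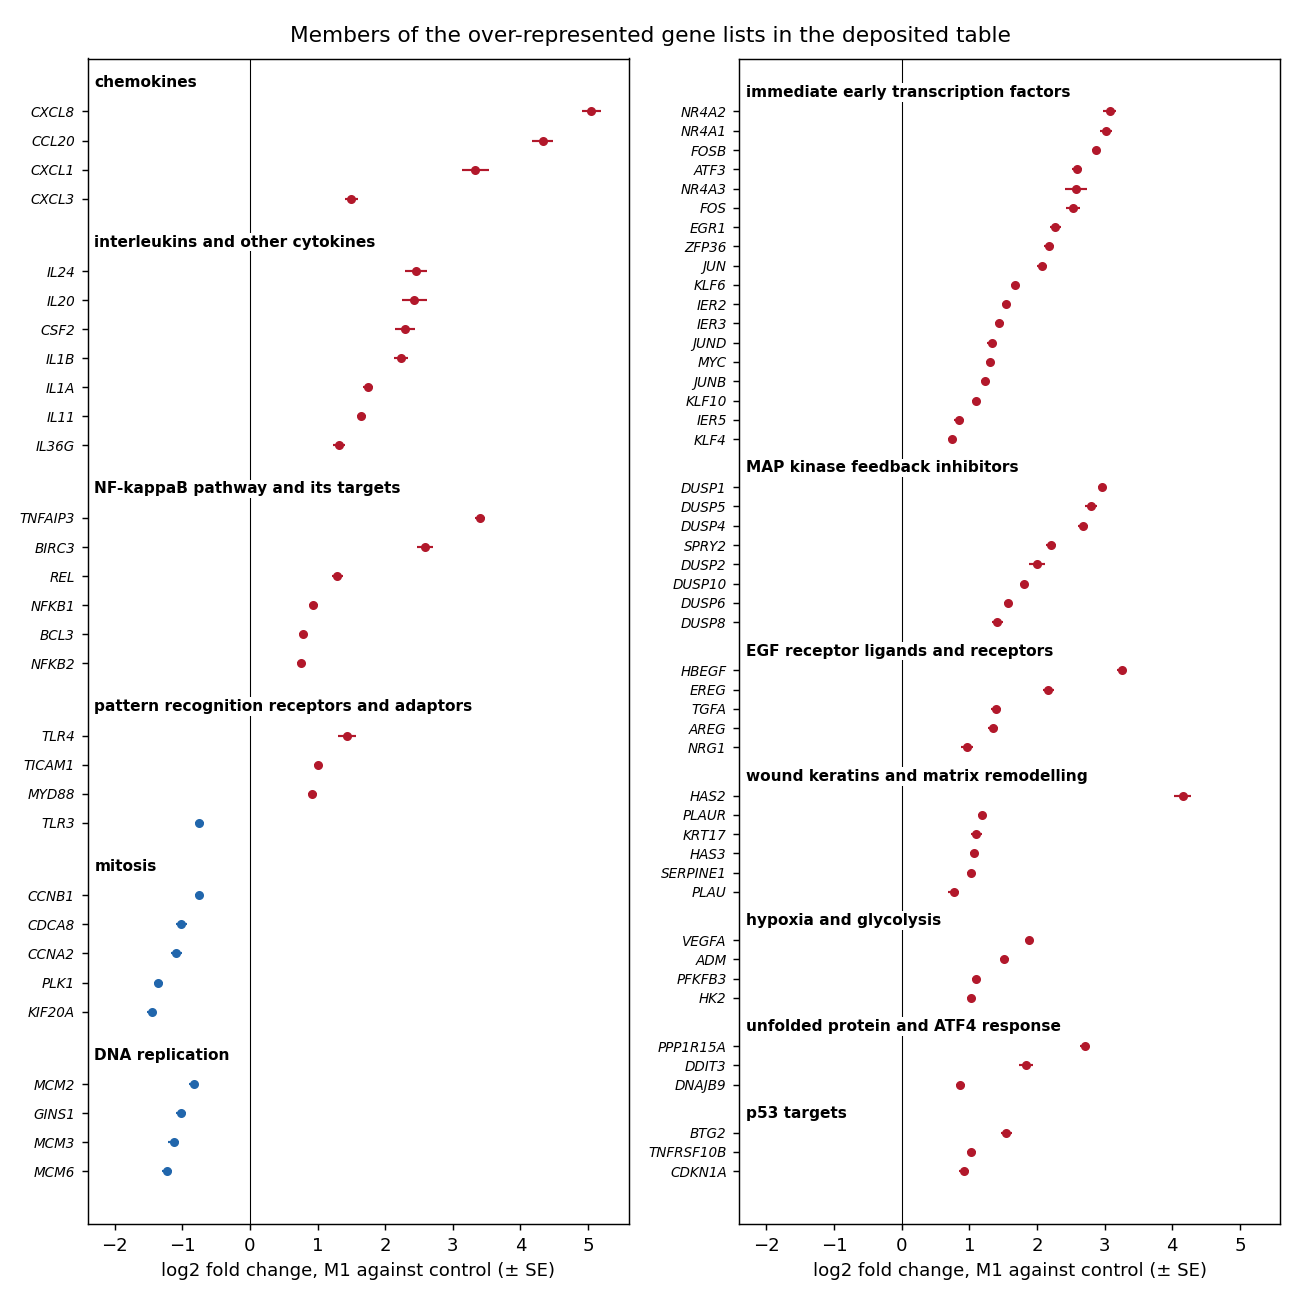
Log2 fold change (x axis, M1 protein against control) with its SE for each member, found in the authors' table, of the 13 gene lists that were over-represented there. Red points are higher and blue points lower with M1 protein; all 18 immediate early genes lie above 0, and the 5 mitosis and 4 DNA replication genes lie below it.

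Several other lists had few or no members in the table. RNASE7, a skin antimicrobial ribonuclease, was the only one of 16 antimicrobial genes there and rose by 2.28 ± 0.15 (SE) on the log2 scale. LAMB3 (0.75 ± 0.06 SE, 1 of 14 basal keratinocyte genes) and the tight junction gene CLDN1 (0.89 ± 0.06 SE, 1 of 17 junction genes) also rose. HSPA1A fell by 0.72 ± 0.06 (SE, 1 of 10 heat shock genes), with a near-identical copy that may share its signal. The adjusted p for over-representation lay between 0.392 and 0.481 for these 4 lists. The table held 0 of 22 interferon-stimulated genes, 0 of 22 terminal differentiation genes, 0 of 21 cholesterol synthesis genes, 0 of 14 NRF2 targets and 0 of 11 genes of TGF-beta and BMP feedback. It also held 0 markers of fibroblasts, leukocytes, endothelium or melanocytes, 0 small nucleolar RNAs and 0 ribosomal protein genes, and 1 replication-dependent histone gene, which was lower. Absence from the table does not show that a gene was unchanged, since 6748 of the probe sets past the test carry no name here. Every list member in the table passed the limma test over all probe sets, and also adjusted over the list alone; as the authors chose the table on these samples, neither is independent evidence.

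Over all probe sets, 7245 of 22119 passed an adjusted p of 0.05 in limma, 2555 higher and 4690 lower with M1 protein. Of these, 790 higher and 1298 lower ones changed over 1.5-fold, and 334 higher and 247 lower ones over 2-fold, so rises led among the largest changes. The higher share was 35.3% as deposited; with each array centred on its median, 3578 probe sets were higher and 3670 lower, a share of 49.4%. Centring shifts every probe set alike and moved the median log2 change of all probe sets from 0.0032 to 0.064. All M1 arrays lay on the same side of all control arrays in 46.5% of the probe sets, where chance gives 10%. Names covered 19 of the 20 largest rises but only 3 of the 20 largest falls. The largest unnamed rises were those of probe sets 16743735 (log2 fold change 2.87 ± 0.25 SE) and 16788697 (2.68 ± 0.49 SE), and the largest unnamed falls were those of 17094224, which fell by 2.29 ± 0.17 (SE), and 16998059, which fell by 2.16 ± 0.22 (SE).

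In the authors' deposited table, 303 probe sets were higher and 194 lower. All 497 passed the limma test, with a largest adjusted p of 0.000463. They had been selected on the same arrays, so this was largely assured and is no independent evidence. The authors' deposited table gave a fold change of 32.9 for CXCL8, 20.2 for CCL20 and 17.7 for HAS2, taken from means of unlogged signals. Its SAM score, the group difference over its spread plus a constant, was 5.97 for CXCL8 and -3.02 for ZNF681 in the authors' deposited table.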

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

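The direction and the call of each of the 72 genes the rule took held under every alternative run on it (1006 gene and setting pairs, largest limma adjusted p 0.00298), and 0 called probe sets changed sign in any refit. The signs were largely fixed in advance. The groups did not overlap in 7234 of the 7245 called probe sets, so leaving out a sample could not reverse these. The replicate block and the variance priors leave the fold changes as they were, so only calls were at risk there. Keeping only named probe sets, all of them called, put neither at risk. Without each sample in turn, 5386 to 6763 probe sets were called, 1883 to 2421 higher and 3503 to 4342 lower. The 1.5-fold limit left 2088 (790 higher, 1298 lower) and the named probe sets alone 497 (303 and 194), fewer by construction. Other tests gave other counts, with 714 (396 and 318) for the equal-variance t-test at an unadjusted p under 0.0001. That limit is the stricter, as the same t-test with Benjamini-Hochberg called 6024. Among tests chosen after the data were seen, the authors' selection as rebuilt gave 497 (303 and 194) and its score limits alone 1124 (508 and 616). All probe sets past these score limits were also limma calls. The unequal-variance t-test with Benjamini-Hochberg gave 3864 (1438 and 2426), and why it called fewer was not tested. The other settings stayed within 1.5 times the counts as reported, with 7061 after quantile normalization (3026 higher, 4035 lower) and 7248 after median centring (3578 and 3670). With the replicate number as a block, 5821 were called (2047 higher, 3774 lower) and no named gene's call changed. Whether the numbers pair the samples stays undecided. Deviations of same-numbered samples from their group means correlated at -0.12, -0.12 and -0.0011, and no sample correlated best with its own number. These values give no sign of pairing but cannot exclude it, as deviations from the mean of so few samples depend on each other. The direction test of the lists rests on signs that no setting changed, so rerunning it says nothing about its stability. Of the lists, 13 were over-represented against the brighter probe sets alone, as many as against all. Only the background (16588) and the table size (492) were cut there. List sizes and member counts stayed as they were, so this check could change little. Camera with an estimated correlation and fry were not run, for want of names of unselected probe sets. Signal limits the dim probe sets: those below the 25th percentile of mean signal gave 539 of the 7245 calls.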

Other observations

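The tests of annotation terms, of the direction of ZNF and ZFP genes and of the authors' t-test step were chosen after the data were seen. The biological process terms in the authors' annotation gave a second grouping of the table, which partly overlaps the fixed lists. Among 400 annotated genes of the table, 12 of 37 terms with at least 10 genes differed in their balance of higher and lower genes (Fisher's exact test, two-sided, Benjamini-Hochberg over 37 terms), 9 toward higher and 3 toward lower. All 18 anti-apoptosis genes were higher (adjusted p = 0.00228), among them SOCS3 (log2 fold change 1.93 ± 0.12 SE) and MCL1 (0.93 ± 0.06 SE). The apoptosis term, which also holds pro-death genes such as PMAIP1 (1.67 ± 0.06 SE), had 28 higher and 4 lower genes (adjusted p = 0.0124). The DNA replication term had 2 higher and 12 lower genes (adjusted p = 0.00228); it holds the 4 table members of the fixed DNA replication list, whose own direction did not pass Fisher's exact test (adjusted p = 0.0823). In that term RFC4, a clamp loader subunit, fell by 1.11 ± 0.06 (SE). DNA repair had 4 higher and 10 lower ones (adjusted p = 0.0361), where EME1 fell by 1.25 ± 0.07 (SE) and BLM fell by 0.91 ± 0.08 (SE). The genes named here were chosen after their values were seen, and the table itself was selected on these samples.

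Genes outside the fixed lists, singled out after their values were seen, were also among the large rises. IL1RL1, the receptor of interleukin-33, rose by 2.91 ± 0.11 (SE) on the log2 scale, BMP2 by 2.72 ± 0.08 (SE) and the activin subunit gene INHBA by 2.39 ± 0.09 (SE). FST, which encodes the activin antagonist follistatin, rose by 2.10 ± 0.05 (SE), so the ligand subunit and its antagonist rose together. LCE1F, a late cornified envelope gene, rose by 2.86 ± 0.10 (SE) although 0 of 22 terminal differentiation genes were in the table. All 5 passed the limma test with adjusted p-values between 3.14e-06 and 1.02e-05.

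As for the number of called probe sets, the 6 samples make 10 splits into groups of 3, too few for a share under 0.05. The real split, the 1 that gave as many, called 7245 probe sets and the highest of the others 0.

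Falls outnumber rises among all called probe sets but not in the authors' table. Past the SAM score limits alone, 45.2% of 1124 probe sets were higher, and the t-test step, which removed 68.5% of the lower ones and 40.4% of the higher ones, raised this to 61.0% in the table. All 627 removed probe sets passed limma. Rises also led without that step among limma calls over 2-fold (57.5% higher). Of the 1124, the lower ones changed less (median 0.953 against 1.13 on the log2 scale) and were dimmer (median signal 8.06 against 9.14). The t-test p is set by the size of the change and the spread within the groups, so signal could act only through these. How much each contributed to the uneven removal was not tested. The lower ones also varied more between M1 arrays, with a median SD 1.66 times that of higher ones (permutation p = 1e-04, the smallest that 10000 draws can give). The permutation was over probe sets, which share the same 3 M1 arrays, so this p-value does not measure the spread between samples. Between M1 replicates 1 and 3 alone the median gap was 1.09 times as large, so replicate 2 may account for much of the difference. Between control arrays the lower ones varied less (median SD 0.0715 against 0.0794 for higher ones). After quantile normalization 42.9% of calls were higher, which argues against unequal array widths as the whole reason for the excess of falls, while median centring gave 49.4%, a rise fixed by its shift of every probe set alike (median change 0.0032 before and 0.064 after), which leaves array centring undecided. A gene list taken from the table may therefore understate the falls, and a true excess of falls after M1 protein stays open as well.

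Genes with ZNF or ZFP symbols, a group noticed in the table and then tested on it, were lower in 21 of 24 cases (ZFP36 and its relatives left out, ZBTB14 and ZFP69 counted by their older symbols), against 172 of 471 other genes (Fisher's exact test, two-sided, p = 7.21e-07). Not all zinc finger genes shared this direction: 13 genes of other C2H2 zinc finger families in the table, EGR1, KLF4, KLF6 and KLF10 among them, were all higher. ZBTB14 belongs to such a family by its current symbol but is counted above by its older symbol. It fell by 1.15 ± 0.07 (SE) on the log2 scale. With the 13 genes added, 21 of 37 were lower, against 172 of 458 other genes (Fisher's exact test, two-sided, p = 0.0236). All 21 belong to the ZNF and ZFP group that prompted the test, so this p-value gives no support for a fall of zinc finger genes in general. Permuting directions within 3 classes of mean signal gave a permutation p = 0.00025 (13.1 lower ZNF or ZFP genes by chance), so low signal does not account for the pattern alone. Lower genes had the longer median span (24731 against 15995 bp) but ZNF or ZFP genes did not (18843 against 20279 bp for others), which argues against gene span, and a permutation within 3 classes of span (p = 2e-05, 10.2 by chance) adds little to this. Probes shared between ZNF paralogues were not tested and stay open, as does an effect of M1 protein on these transcripts.

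M1 replicate 2 stood 11.3% farther from the controls on the first principal component than the other M1 arrays did. A larger response of all called probe sets would need slopes over 1.1 against the other M1 arrays in both directions; the slope was 1.19 among lower but 0.955 among higher probe sets, which argues against it. After quantile normalization the excess was 10.5% (bootstrap SD 0.595, over probe sets), far from the 5% or less set in advance for a narrower distribution of its values, which argues against that as the whole reason. A stronger fall of the lower probe sets in that sample alone may be technical or biological, and no label separates these. The named genes kept their calls without this sample.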
